A study of Mus musculus with 6 samples.

How the data were processed

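The series holds RNA-seq of whole tibialis anterior muscle from 6 male C57BL/6J mice, 14 days after glycerol injection, 3 with a control treatment and 3 with melatonin, per the labels. The labels name tibialis anterior as the tissue, while their RNA extraction text names a back muscle; the tissue label was used. Dose, route and timing of melatonin are not given in the sources used here.

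The authors deposited 1 table of raw read counts per gene for all 6 libraries, with mouse Ensembl gene identifiers. Per the submitters' processing notes, the tools were FastQC 0.11.2, Trimmomatic 0.36, HISAT2 2.0, bedtools 2.26.0, StringTie 1.3.3b and DESeq2 1.12.4 and the genome build was mm10; which tool made the counts, the annotation, the treatment of strand and of reads with several matches are not given in the sources used here. The counts are whole numbers, the smallest total of a gene over the libraries is 28, and 16203 of the 16289 genes have a count in every library, so the deposited table had been filtered on low counts before. Columns were matched to samples by their names, a treatment code and a replicate number, and all were used. Without the strand of counting, reads of a gene and of an antisense partner may be mixed, and 6014 genes share exon bases with another annotated gene.

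Symbols were found for 16260 genes, and positions, lengths and GC content of the longest transcript were taken from GENCODE release M21 on GRCm38, the same assembly as mm10 (99.8% of genes had a length). Total counts ran from 39310361 to 48879045 per library. At such depth counting error is small for genes above 1 CPM, and the spread between mice sets the precision; the floor of 3 counts given for an all-zero group covers counting error only. Replicates of a group differed far beyond sampling noise (chi-square per degree of freedom 65.9 to 181), so none was counted as a repeat of another. The series' text calls the 3 samples of a group biological replicates.

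The main test, fixed with the gene lists, the rule for named genes and the first set of other settings before the data were examined, was edgeR 4.0.16's quasi-likelihood test (R 4.3.3) with TMM factors and the filterByExpr filter, which kept 16259 genes, on all 6 libraries with no covariate. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are scaled by the TMM factors. Log CPM for principal components and correlations used a prior count of 2.

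Gene lists (44 with at least 3 tested members, covering cell types of injured muscle, metabolism, fibre types, stress and sample quality) were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were the alternatives. For each list, members were also counted that passed over all genes and adjusted over the list alone.

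Named genes were, first, the 12 highest and 12 lowest fold changes that passed with a mean of at least 1 CPM and no overlap between groups, leaving out predicted and clone-named genes. Then came the 4 leading members of each list that passed, up to 3 members passing over all genes in other lists, and a set of genes fixed beforehand. Other genes are named only where the text says that they were chosen after their values were seen, as partners that share bases with a named gene, or as members of the clock score. Of the genes that this rule picks, 2 are not reported here.

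The other settings fixed beforehand were library size alone, RLE and upper quartile factors, no filter, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom with and without sample weights, a replicate block, other thresholds and leaving out each library in turn. Added after the data were seen were corrections for transcript length and for length with GC content (a spline with 4 degrees of freedom fitted per library on genes with a mean log2 CPM above 0), overlapping genes on the same strand with at least 100 shared exon bases merged, the models Gm20708 and Gm28036 each summed with the gene that shares most of its exon bases, a fit without mitochondrial genes and their chromosome 1 copies, and list tests combining the block with an estimated correlation. Settings meant for normalized values were not run, as the table holds counts. Matched gene sets were 10000 random sets drawn from the 100 nearest genes of each member in transcript length and mean expression.

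The scripts were tested on simulated counts for this comparison, 16259 genes, of which 67 were changed 1.5-fold, 67 2-fold and 66 4-fold. The edgeR test recovered 0% of 1.5-fold, 20.9% of 2-fold and 92.4% of 4-fold changes, with 7 false calls among 82. DESeq2 recovered 4.5%, 53.7% and 97%, with 28 false calls among 131 (21.4%). Camera with the preset correlation, camera with an estimated correlation and fry each found 2 of 2 lists shifted by 0.7 and called 0 of 20 unshifted ones. The simulated genes were drawn independently of each other. This run therefore cannot tell whether the preset correlation is high enough for the real lists. The length correction took an added slope of -0.4 log2 units per doubling of length to -0.008 and false calls from 795 to 5, while true calls went from 110 to 75. That slope was steeper than the -0.136 of the real fold changes. Without an added trend edgeR made 82 calls, 7 of them false, so the fewer true calls do not show a loss of power. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.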

Results

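RNA-seq read counts per gene were measured in the tibialis anterior, a muscle of the front of the lower leg, of 12-week-old male C57BL/6J mice. Glycerol, which destroys muscle fibres and is followed by regeneration with deposits of fat, had been injected 14 days before the muscle was taken. The 6 libraries fell into 2 groups of 3 mice: glycerol with a control treatment (glycerol) and glycerol with melatonin, a hormone of the pineal gland (glycerol+melatonin). Total counts were 46569255, 48879045 and 39310361 in the glycerol libraries and 45261264, 47945178 and 41204718 in the glycerol+melatonin libraries. Each library came from a separate animal. The single comparison that the design implies asks which transcripts of the injured muscle differed when melatonin was given. Libraries were alike, with correlations of log2 CPM (counts scaled to a common library total of 1e6) of 0.964 to 0.977 within groups and 0.947 to 0.972 between groups. The first principal component, with 39% of the variance, placed the glycerol libraries at -41.4, -47.0 and -9.35 and the others at 15.3, 33.8 and 48.6.

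In glycerol+melatonin muscle, 9 genes passed as lower and 3 gene models with Gm symbols as higher. For Afmid, Gm20708 and Gm28036 the change was uncertain at the level of the locus, as described below. The enzyme that starts glycerolipid synthesis from glycerol-3-phosphate, Gpam, fell 4.37-fold, from 66.9 ± 12.2 to 15.3 ± 3.22 CPM (mean ± SD, n = 3 per group), and the cationic amino acid transporter Slc7a2 fell 5.45-fold, from 47.3 ± 14.3 to 8.67 ± 1.24 CPM. The thiamine transporter Slc19a2 fell 5.28-fold, the G protein subunit gene Gnal 7.33-fold and the membrane protein gene Tmem87b 6.29-fold. The phosphatase gene Ppm1a fell 3.23-fold from 118.5 ± 14.6 CPM and the scaffold protein gene Dlg1 3.44-fold from 21.0 ± 3.74 CPM. Afmid, which encodes the kynurenine formamidase of tryptophan breakdown, fell 4.62-fold, and the gene model Gm20708, which overlaps it, rose 6.71-fold.

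The log2 fold changes were -2.13 ± 0.21 (SE) for Gpam, -2.45 ± 0.24 for Slc7a2 and -2.87 ± 0.28 for Gnal, each with adjusted p = 0.0148 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Dlg1 was at -1.78 ± 0.20 (edgeR adjusted p = 0.0334). Tmem87b (-2.65 ± 0.32), Slc19a2 (-2.40 ± 0.29), Afmid (-2.21 ± 0.26) and Ppm1a (-1.69 ± 0.21) had edgeR adjusted p = 0.0419. For all 12 genes the 2 groups did not overlap. As the genes were picked by p-value on these same values, this is no further evidence. Of genes not so picked, 10% would show such a separation by chance. On the mouse genome build GRCm38, Gpam (ENSMUSG00000024978) lies on chromosome 19 from 55067268 to 55127238 and Slc7a2 (ENSMUSG00000031596) on chromosome 8 from 40862396 to 40922308. Gnal (ENSMUSG00000024524) lies on chromosome 18 from 67088216 to 67226792. Gnal shares 852 exon bases with Mppe1 on the other strand (Mppe1 -0.13 ± 0.23).

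The 3 gene models that rose were each chosen after its values were seen. Gm28036 went from 0.181 ± 0.141 to 10.5 ± 1.14 CPM (5.82 ± 0.50 on the log2 scale) and Gm20708 from 1.20 ± 0.323 to 8.04 ± 1.35 CPM (2.75 ± 0.26), both with edgeR adjusted p = 0.0148. Gm20708 shares 1566 exon bases with Afmid on the same strand, and the 2 summed were at 10.6 ± 1.62 and 10.1 ± 1.85 CPM (-0.072 ± 0.203, edgeR adjusted p = 0.873). Gm28036 shares 3755 exon bases with Cpne1, which was at 26.8 and 15.4 CPM, and the 2 summed were at 27.0 ± 0.55 and 25.9 ± 1.60 CPM (-0.059 ± 0.137, edgeR adjusted p = 0.839). On the same strand Gm28036 also shares 2182 exon bases with Rbm12 and 256 with Nfs1. Summed with Cpne1, Rbm12 and Nfs1, it was at 119.3 ± 9.76 CPM in glycerol and 100.2 ± 17.2 CPM in glycerol+melatonin. The change of Afmid and of both models is therefore uncertain at the level of the locus. Gm4613, a processed pseudogene on chromosome 7 (25828602 to 25828877), had 0 counts in the 3 glycerol libraries and 34, 61 and 65 in the others (edgeR adjusted p = 0.0439). By total counts, without the TMM factors, this was 53.5-fold higher over a floor of 3 counts for the glycerol group as a whole.

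**Figure D1:**
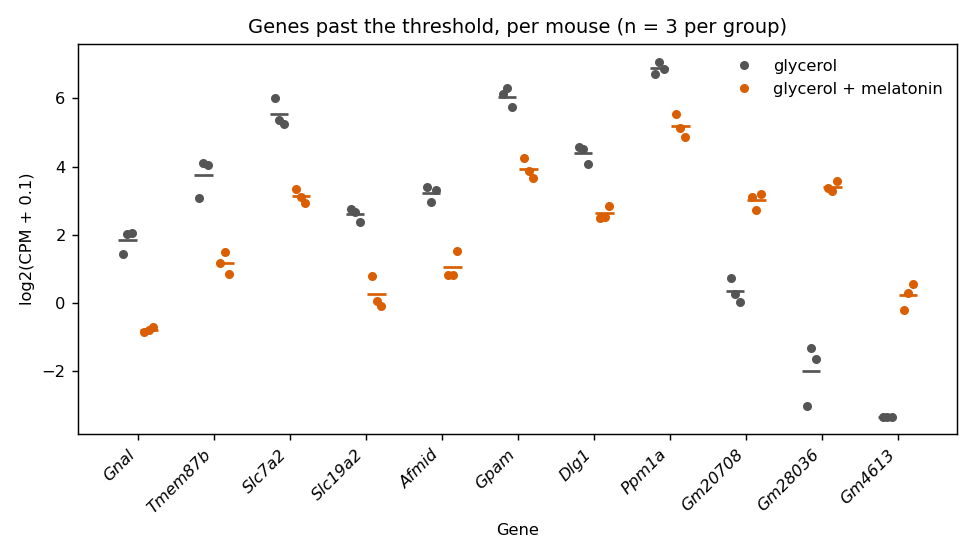
Each point is 1 mouse (n = 3 per group, bars are group means), the vertical axis is log2(CPM + 0.1) and the horizontal axis lists 11 of the 12 genes that passed edgeR's threshold. Of those shown, 8 genes are lower in every glycerol+melatonin library than in any glycerol library, and the 3 gene models with Gm symbols are higher.

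In all, 12 of 16259 genes passed (3 higher, 9 lower), and 3170 genes had an unadjusted p under 0.05. By chance alone 813 would be the mean number, but genes vary together. Splits of the 6 libraries into 3 and 3 that mixed the groups gave up to 1466 such genes by edgeR. Such splits keep part of the real grouping, so that number does not measure chance alone either. DESeq2 called 752 genes (332 higher, 420 lower), 11 of the 12 among them, and limma-voom with sample weights called 199. Correcting for transcript length left 7 genes, with Tmem87b, Slc19a2, Afmid, Ppm1a and Gm4613 no longer passing (edgeR adjusted p 0.0505 to 0.0855). Single mice moved the count too: 6 genes passed without glycerol replicate 1 (5 of the 12), 11 without glycerol replicate 2 (5 of the 12) and 27 without glycerol replicate 3 (7 of the 12). Of the other group, 25 passed without glycerol+melatonin replicate 1 (9 of the 12), 11 without its replicate 2 (2 of the 12) and 24 without its replicate 3 (8 of the 12).

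Fatty acid oxidation genes fell as a group, with 26 of 30 measured members below 0 and a median log2 fold change of -0.39 (camera adjusted p = 1.39e-05; adjusted p = 0.819 with an estimated correlation). No member passed by edgeR, either over all genes or adjusted over the list alone. The level of the list per mouse was 0.188, 0.249 and 0.265 in glycerol and 0.16, -0.23 and -0.573 in glycerol+melatonin, where replicate 1 lay near the glycerol mice. Fast fibre genes (0.212, -0.133 and -0.476) and glycolysis genes (0.203, -0.092 and -0.46) moved alike in these 3 mice. The leading members were Acsl1, which activates long-chain fatty acids (-1.42 ± 0.31, 218.5 ± 46.3 to 81.6 ± 34.7 CPM), Pdk4, an inhibitor of pyruvate use (-0.92 ± 0.28), and the peroxisomal enzyme Ehhadh (-0.67 ± 0.22), with edgeR adjusted p from 0.132 to 0.185. Of 22 lipogenesis genes, 1 passed over all genes (Gpam) and 2 were lower adjusted over the list alone (Gpam and Fads2, the latter chosen after its values were seen), while the list as a whole did not pass (camera adjusted p = 0.186).

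Markers of mature fat cells did not pass as a list: 9 of 21 were above 0 and 12 below, 0 passed adjusted over the list alone, and the median was -0.14 (camera adjusted p = 0.745). Adiponectin (Adipoq) was at 10.6, 5.18 and 37.8 CPM in glycerol and at 18.4, 9.65 and 6.02 CPM in glycerol+melatonin, a log2 fold change of -0.65 ± 0.68 (edgeR adjusted p = 0.612), and the lipid droplet gene Plin1 was at -0.20 ± 0.47. Glycerol replicate 3 was the highest library for 16 of the 21 genes. Without it the list was at camera adjusted p = 0.0687 in the other direction, Adipoq at 0.53 and Plin1 at 0.41 (0.05 without glycerol+melatonin replicate 3). Leaving out another library instead gave a camera adjusted p as low as 0.0641 with the list still lower. Fabp4, which endothelium also expresses, was at 0.56 ± 0.22 (edgeR adjusted p = 0.221) and the fat cell regulator Pparg at 0.06 ± 0.19 (edgeR adjusted p = 0.892). Lipolysis genes (13 tested, camera adjusted p = 0.481) and cholesterol synthesis genes (17 tested, 0.248) did not pass, nor did thermogenic genes (10 tested, camera adjusted p = 0.771).

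Genes of connective tissue fell in 4 groups. Markers of fibro-adipogenic progenitors, the stromal cells that give rise to fat and fibrous tissue in injured muscle, had 17 of 23 members below 0 and a median of -0.46 (camera adjusted p = 4.14e-04; adjusted p = 0.819 with an estimated correlation). Per mouse the list was at -0.119, 0.439 and 0.329 in glycerol and at -0.211, -0.143 and -0.42 in glycerol+melatonin, with glycerol replicate 1 apart from its group. After a correction for transcript length the median was -0.29. Of these markers, 6 were lower adjusted over the list alone and 0 over all genes, led by the microfibril gene Fbn1 (-0.79 ± 0.14, 139.9 ± 8.79 to 81.0 ± 5.61 CPM), Osr1 (-0.65 ± 0.16), Dcn (-0.81 ± 0.21) and Hsd11b1 (-0.92 ± 0.27). Pdgfra, the receptor that marks these cells, was at -0.71 ± 0.22 (edgeR adjusted p = 0.176). Extracellular matrix genes fell with 26 of 31 below 0 and a median of -0.31 (camera adjusted p = 0.00115; adjusted p = 0.819 with an estimated correlation), and 2 were lower adjusted over the list alone, the collagen crosslinker Loxl2 (-0.74 ± 0.16) and Col12a1 (-0.81 ± 0.18). Timp2 was at -0.44 ± 0.15, Col6a3 at -0.62 ± 0.22, Col1a1 at -0.39 ± 0.24 and Col3a1 at -0.37 ± 0.22, none passing by edgeR.

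Cartilage and bone genes fell with 8 of 11 below 0 and a median of -0.38 (camera adjusted p = 0.00583; adjusted p = 0.727 with an estimated correlation), and 2 were lower adjusted over the list alone. These were bone sialoprotein Ibsp, from 4.18 ± 1.05 to 0.408 ± 0.392 CPM (-3.37 ± 0.62, edgeR adjusted p = 0.111), and the hypertrophic cartilage collagen Col10a1, from 1.33 ± 0.309 to 0.362 ± 0.0575 CPM (-1.86 ± 0.34, edgeR adjusted p = 0.107), with Ogn at -0.55 ± 0.18 and Runx2 at -0.38 ± 0.20. The cartilage and bone median was -0.22 after a correction for transcript length. Tendon genes fell with 10 of 12 below 0 (median -0.51, camera adjusted p = 0.029; adjusted p = 0.819 with an estimated correlation) and 0 passing adjusted over the list alone, led by Fmod (-0.99 ± 0.32), Col11a1 (-0.64 ± 0.23), Thbs4 (-0.57 ± 0.24) and Kera (-0.90 ± 0.41). Per mouse, tendon genes were at 0.139, 0.444 and 0.275 in glycerol and at -0.71, -0.235 and 0.275 in glycerol+melatonin, so replicate 3 lay at the glycerol level. The tendon call was lost without glycerol replicate 3 (camera adjusted p = 0.0687) and without glycerol+melatonin replicates 1 (0.267) or 2 (0.0764). The matrix call was lost without glycerol+melatonin replicate 1 (camera adjusted p = 0.111). Gene sets matched to the matrix list on transcript length and expression had medians from -0.40 to -0.07, a range that holds the observed -0.31.

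Genes of newly formed fibres rose as a group, with 20 of 23 above 0 and a median of 0.39 (camera adjusted p = 0.00115; adjusted p = 0.819 with an estimated correlation). The groups overlapped per mouse: the list was at 0.107 in glycerol replicate 1 and 0.009 in glycerol+melatonin replicate 1. Glycerol replicate 2 stood apart at -0.511, as it did for slow fibre (-0.944) and denervation (-0.307) genes. The muscle LIM protein gene Csrp3 was the 1 member higher adjusted over the list alone, from 25.8 ± 8.11 to 86.6 ± 38.9 CPM (1.75 ± 0.35, edgeR adjusted p = 0.122). The fusion factor Mymx was at 0.99 ± 0.29, the fetal acetylcholine receptor subunit Chrng at 0.91 ± 0.33, the myogenic factor Myog at 0.64 ± 0.22, embryonic myosin Myh3 at 0.83 ± 0.37 and neonatal myosin Myh8 at 0.12 ± 0.24, none passing by edgeR. Muscle stem cell genes did not pass (22 tested, 12 above 0, camera adjusted p = 0.517), with Pax7 at 0.35 ± 0.31 and Myod1 at 0.24 ± 0.31. Fast fibre genes had 17 of 25 below 0 and a camera adjusted p of 0.0515, which became 0.00116 once transcript length was corrected for, and it passed without glycerol replicate 1 (0.0454) or 3 (0.0433) and without glycerol+melatonin replicate 1 (6.74e-04). Fast myosin Myh4 was at -0.58 ± 0.31, and slow myosin Myh7 was at -0.75 ± 0.98, 1.03 without glycerol replicate 1.

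Immediate-early and heat shock genes, which cells switch on within minutes to hours of a stimulus or stress, rose as a group. Of 27 members, 24 were above 0, 15 were higher adjusted over the list alone and 0 over all genes, with a median of 0.51 (camera adjusted p = 1.77e-09; adjusted p = 0.727 with an estimated correlation). The AP-1 gene Fos went from 12.1 ± 2.30 to 31.6 ± 6.90 CPM (1.38 ± 0.22, edgeR adjusted p = 0.0788), Jund from 87.8 ± 9.84 to 153.5 ± 4.59 CPM (0.81 ± 0.15), Ier5 from 13.7 ± 1.53 to 30.2 ± 9.01 CPM and Ier2 from 16.6 ± 3.01 to 30.7 ± 3.27 CPM. The interferon-stimulated list rose with 21 of 27 above 0 (median 0.30, camera adjusted p = 0.00278; adjusted p = 0.819 with an estimated correlation) and 2 higher adjusted over the list alone, Bst2 (1.02 ± 0.18) and the antiviral enzyme gene Oas2 (1.26 ± 0.26). Isg15 was at 1.04 ± 0.31 and Oas1a, one of several near-identical copies, at 0.89 ± 0.28. This call was lost without glycerol+melatonin replicate 3 (camera adjusted p = 0.104). Per mouse the interferon list was at -0.016, -0.378 and -0.056 in glycerol and at 0.052, 0.003 and 0.469 in glycerol+melatonin. Glycerol replicate 2 and glycerol+melatonin replicate 3 thus stood apart from their groups.

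Neutrophil markers rose too, mainly in 1 mouse, with 5 of 5 tested members above 0 and 2 higher adjusted over the list alone (median 0.97, camera adjusted p = 0.0249; adjusted p = 0.819 with an estimated correlation). S100a9, among the most abundant neutrophil transcripts, had 2, 0 and 4 counts in glycerol and 14, 89 and 340 in glycerol+melatonin, the last being replicate 3 at 7.23 CPM. Csf3r was at 0.82 ± 0.29, Lcn2 at 1.32 ± 0.66 and Mmp8 at 0.97 ± 0.61. The call was lost without glycerol+melatonin replicate 3 (camera adjusted p = 0.216), without glycerol replicate 3 (0.0706) and with library size alone (0.0561). Macrophage markers did not pass (9 of 27 above 0, camera adjusted p = 0.544), with Adgre1 at -0.58 ± 0.30 and Cd68 at -0.17 ± 0.18, or 0.06 when scaled by library size alone. Lymphocyte markers (21 tested, camera adjusted p = 0.784) and cytokine genes (27 tested, camera adjusted p = 0.27) did not pass either.

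**Figure D2:**
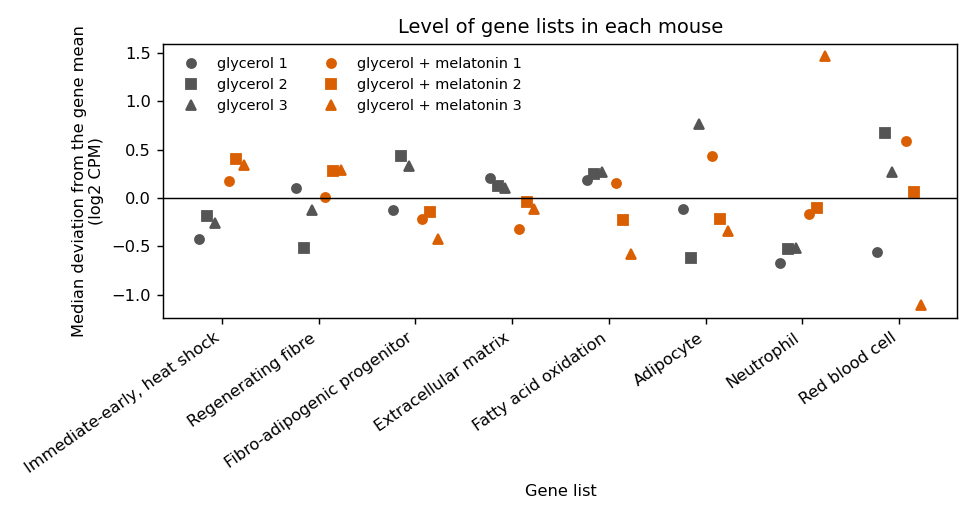
Each point is 1 mouse, and the vertical axis is the median over a list's genes of the deviation from the gene's mean log2 CPM. Immediate-early genes lie from 0.18 to 0.40 in the 3 glycerol+melatonin mice and from -0.43 to -0.19 in the 3 glycerol mice, while fat cell markers peak in glycerol replicate 3 (0.76) and neutrophil markers in glycerol+melatonin replicate 3 (1.47).

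As lists, genes of the translation machinery and of the respiratory chain encoded in the nucleus rose, and mitochondrially encoded genes fell. The oxidative phosphorylation and mitochondrial ribosome lists no longer passed after a correction for transcript length (medians 0.10 and 0.09). Of 82 cytosolic ribosomal protein genes, 81 were above 0, 37 were higher adjusted over the list alone and 0 over all genes, with a median of 0.57 (camera adjusted p = 5.15e-24; adjusted p = 0.819 with an estimated correlation). Per mouse the list was at -0.532, -0.445 and 0.07 in glycerol and at 0.244, 0.318 and 0.349 in glycerol+melatonin, with glycerol replicate 3 apart from its group. Rps28 was at 0.92 ± 0.17, Rpl37 at 0.81 ± 0.18, Rps12 at 0.94 ± 0.21 and Rpl35a at 0.87 ± 0.20. These genes have many processed pseudogenes, and how the authors' counting treated reads that fit several copies is not given in the sources used here. Nuclear genes of oxidative phosphorylation had 68 of 83 above 0, 0 passing adjusted over the list alone and a median of 0.37 (camera adjusted p = 7.14e-07; adjusted p = 0.819 with an estimated correlation), led by the complex I genes Ndufa3 (0.57 ± 0.14), Ndufa5 (0.72 ± 0.19), Ndufa7 (0.56 ± 0.16) and Ndufa1 (0.69 ± 0.20). The groups overlapped per mouse, with glycerol replicate 3 at 0.034 and glycerol+melatonin replicate 3 at -0.07. Mitochondrial ribosomal protein genes had 55 of 78 above 0, 0 passing adjusted over the list alone and a median of 0.16 (camera adjusted p = 0.0255, or 0.819 with an estimated correlation). They were led by Mrpl52 (0.68 ± 0.16), Mrpl57 (0.51 ± 0.13), Mrpl54 (0.48 ± 0.15) and Mrps7 (0.46 ± 0.15). Here too the groups overlapped, with glycerol replicates 2 and 3 at -0.107 and 0.007 and glycerol+melatonin replicate 3 at -0.113.

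The 7 tested genes of the mitochondrially encoded list were all below 0, 2 of them lower adjusted over the list alone. Their median was -0.63 (camera adjusted p = 0.00583, or 0.819 with an estimated correlation). The deposited counts also hold genes of the mitochondrial genome outside this list. The groups overlapped per mouse, with the list at -0.256 in glycerol replicate 3 and at 0.014 in glycerol+melatonin replicate 3. Complex I gene mt-Nd4l was at -1.69 ± 0.40 and ATP synthase gene mt-Atp6 at -2.42 ± 0.68, with mt-Co1 at -0.65 ± 0.37 and mt-Nd1 at -0.63 ± 0.38. The fall of mt-Atp6 came from glycerol replicates 1 and 2, with 21958 and 17546 CPM against 2505 CPM in replicate 3 and 3020, 1816 and 3027 CPM in glycerol+melatonin. Mitochondrial genes took 17.9%, 14.9% and 10.3% of counts in the glycerol libraries and 11.2%, 8.70% and 12.8% in the others. The call was lost without glycerol+melatonin replicate 2 (camera adjusted p = 0.107). The gene mt-Co3 and its nuclear copy Gm28437, both chosen after their values were seen, had near-equal means of 15027 and 14861 CPM in glycerol.

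Fold changes in this comparison followed transcript length. Across 13933 genes, which are not independent replicates, the log2 fold change correlated with log2 length at r = -0.28 (Spearman's rho -0.32), and its median went from 0.48 for transcripts up to 500 bases to -0.16 above 8000. Glycerol replicates 1 and 2 had slopes of 0.11 log2 units per doubling of length, glycerol replicate 3 of -0.007, and the glycerol+melatonin libraries of -0.09, -0.06 and -0.06. After a correction for length the ribosomal protein genes kept a median of 0.36 (camera adjusted p = 2.73e-12). The oxidative phosphorylation list went from a median of 0.37 to 0.10 (camera adjusted p = 0.183) and the mitochondrial ribosome list to 0.09 (0.696), and neither passed. The mitochondrial ribosome call was also lost without glycerol replicate 1 (camera adjusted p = 0.0592), glycerol replicate 2 (0.0713) or glycerol+melatonin replicate 1 (0.616).

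**Figure D3:**
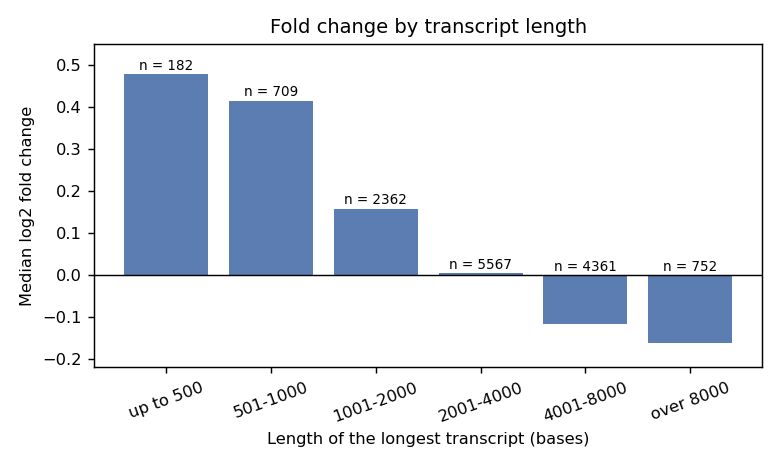
Bars give the median log2 fold change (glycerol+melatonin over glycerol) of genes grouped by the length of their longest annotated transcript, with the number of genes above each bar. The median is 0.48 for the 182 genes up to 500 bases and -0.16 for the 752 genes above 8000 bases.

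**Figure D4:**
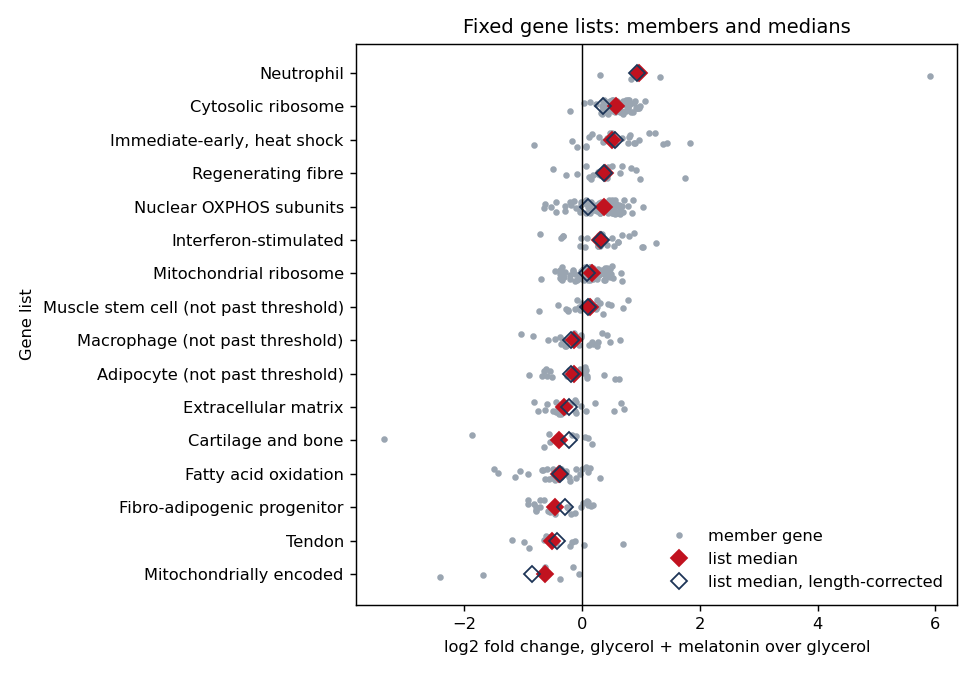
Grey points are the log2 fold changes of the member genes, filled diamonds the list medians and open diamonds the medians after correction for transcript length. The 13 lists that passed with camera's preset correlation are shown with 3 that did not (fat cell, muscle stem cell and macrophage markers).

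Of 44 gene lists tested, 13 passed (7 higher, 6 lower), and 0 passed with an estimated correlation between genes or by fry, a rotation test of the list alone (lowest adjusted p 0.727 and 0.0759). Melatonin-related genes were scarcely measured: 4 of 9 were tested (camera adjusted p = 0.981). The receptor genes Mtnr1a and Mtnr1b, like the thermogenic gene Ucp1, had no row in the deposited counts, which had been filtered on low counts, and could not be analysed. Clock genes did not pass (7 of 19 above 0, camera adjusted p = 0.233, or 0.0433 without glycerol replicate 3), with Per2 at 0.18 ± 0.21, Nr1d1 at -0.59 ± 0.37 and Dbp at -0.95 ± 0.31, the last sharing 539 exon bases with Sphk2 on the other strand, which was at -0.95 ± 0.16 (edgeR adjusted p = 0.0788). Nr1d1 was at 0.05 without glycerol replicate 1. The mitochondrial regulator Ppargc1a was at -1.03 ± 0.44, the growth factor Igf1 at 0.13 ± 0.18 and the atrophy gene Fbxo32 at -0.30 ± 0.34 (edgeR adjusted p 0.251, 0.721 and 0.645). Igf1 was at -0.02 without glycerol+melatonin replicate 2 and Fbxo32 at 0.002 without glycerol replicate 2.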

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

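The length corrections, the merging of overlapping genes, the fit without mitochondrial genes and the block with an estimated correlation were chosen after the data were seen; the other alternatives were planned. The cause of a moved or reversed value was not tested unless stated. Against 12 genes (3 higher, 9 lower), DESeq2 gave 752 (332 higher, 420 lower), limma-voom with sample weights 199 (100 and 99), a threshold of 0.1 gave 59 (18 and 41), the length correction 7 (5 lower) and merged overlaps 1 higher gene. Leaving out 1 library gave 6 to 27 genes, 2 to 7 higher and 3 to 21 lower. All 12 genes kept their sign without each library in turn. RLE and upper quartile factors, no filter and the fit without mitochondrial genes each kept the same 12 genes. Scaling by library size alone moved the median of all genes to 0.23 from 0.02 and shared 9 of the 12. Of the 13 lists that passed, 0 higher and 0 lower passed with an estimated correlation, by fry, or with the block and an estimated correlation, and all 13 kept their direction in each fit that held them. Single left-out libraries kept 10 to 12 of the 13 calls, the length correction 11.

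The replicate numbers did not pair the samples: deviations of same-numbered libraries from their group means correlated at -0.010, -0.011 and -0.049, and no sample correlated best with its own number. With a replicate block edgeR called 0 genes (0 higher, 0 lower; 2991 at an unadjusted p under 0.05), also with the length correction (0; 2672). Of the 13 lists, 12 kept their calls with the block and 10 with the block and the length correction.

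Of the 12 genes that passed, Gm20708 and Gm28036 had no value of their own with overlaps merged, and the sums that hold them were below 0 (-0.095 and -0.252). The other reversals were of results that had not passed. With sample weights Adipoq was at 0.14, Plin1 at 0.14 and Myh7 at 0.10. Pparg was at -0.021 with the length correction (-0.011 with the block), and Cd68 at 0.057 with library size alone. Lists turned direction at adjusted p of 0.876, 0.962 and 0.747 (growth signalling), 0.778, 0.731 and 0.867 (antigen presentation), 0.502, 0.49 and 0.544 (replication histones) and 0.906, 0.805 and 0.917 (melatonin) with the length, the length and GC, and the length and block corrections. Smooth muscle turned at 0.914 (length), 0.936 (with the block) and 0.924 (library size alone), proteasome at 0.899 and 0.936 (length, with the block) and melatonin at 0.984 by fry.

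Leaving out 1 library, Adipoq ranged from -1.19 to 0.53, Plin1 from -0.65 to 0.41, Pparg from -0.068 to 0.22, Myod1 from -0.082 to 0.58, Myh8 from -0.014 to 0.40, Myh7 from -1.34 to 1.03, Nr1d1 from -0.83 to 0.047, Igf1 from -0.017 to 0.28 and Fbxo32 from -0.56 to 0.002. Some lists turned direction in at least 1 of these fits. Over all of the fits, turned or not, their camera adjusted p ranged from 0.0641 to 0.936 (fat cell), 0.364 to 0.909 (thermogenic), 0.168 to 0.964 (atrophy), 0.208 to 0.936 (macrophage), 0.282 to 0.897 (antigen presentation), 0.101 to 0.919 (lymphocyte), 0.57 to 0.943 (smooth muscle), 0.0516 to 0.943 (erythroid), 0.33 to 0.957 (keratinocyte), 0.661 to 0.969 (melatonin) and 0.108 to 0.934 (replication histones). The low ends for fat cell and erythroid genes came from fits that had not turned. Depth did not limit genes above 1 CPM in both groups; S100a9, Gm4613 and Gm28036 rest on few counts in glycerol (0 to 13 per library).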

Other observations

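Several groups outside the main account held single members that moved although the list did not pass. Among antioxidant genes (27 tested, camera adjusted p = 0.27), 3 were lower adjusted over the list alone: the glutathione peroxidase Gpx1 (-1.57 ± 0.22, 137.4 ± 4.72 to 46.2 ± 13.2 CPM, edgeR adjusted p = 0.0594), Gstm1 (-0.87 ± 0.19) and catalase (Cat, -0.72 ± 0.18). In the TGF-beta and BMP list (25 tested, camera adjusted p = 0.282), the BMP target Id1 was higher adjusted over the list alone (1.32 ± 0.19, edgeR adjusted p = 0.0653) and Tgfbr3 lower (-0.57 ± 0.14). In the growth signalling list (22 tested, camera adjusted p = 0.343) Mef2c was higher (1.10 ± 0.28) and the insulin receptor gene Insr lower (-1.04 ± 0.26), again adjusted over the list alone. Sarcolipin (Sln), an inhibitor of the calcium pump of the sarcoplasmic reticulum, was the 1 slow fibre gene higher adjusted over the list alone (1.42 ± 0.27, 132.6 ± 33.0 to 354.0 ± 112 CPM; 15 tested, camera adjusted p = 0.226, or 0.0137 without glycerol replicate 1). Endothelial genes (17 tested, camera adjusted p = 0.108, or 0.021 and 0.0212 without glycerol+melatonin replicates 1 and 2) held 1 such gene, Rgcc (0.99 ± 0.20). Genes of p53 and apoptosis (19 tested, 0.139) held 2, Bax (0.94 ± 0.22) and Gadd45a (0.63 ± 0.15), and endoplasmic reticulum stress genes (20 tested, 0.544) held 1, Atf3 (1.83 ± 0.40). Cholesterol synthesis held Fdft1 (-0.81 ± 0.17) and the cytokine list Ccl11 (-1.07 ± 0.20), both lower adjusted over the list alone. These genes were named after their values were seen, and none passed over all genes.

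The other lists gave no call over all genes or adjusted over the list alone. Their camera adjusted p values were 0.0594 for mitochondrial biogenesis, 0.122 for Schwann cells and nerve, 0.13 for glycolysis, 0.186 for the proteasome, 0.208 for the cell cycle, 0.436 for both red blood cells and denervation, 0.544 for atrophy, 0.626 for replication histones, 0.724 for keratinocytes, 0.824 for antigen presentation and 0.903 for smooth muscle and pericytes. Leaving out 1 library took some of them past the threshold: Schwann cells and nerve without glycerol replicate 1 (0.0133), the proteasome without glycerol replicate 3 (0.0289) or glycerol+melatonin replicate 3 (0.00761), and glycolysis (0.00371), the cell cycle (0.0433) and mitochondrial biogenesis (0.00909) without glycerol+melatonin replicate 1.

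Except for the clock comparison, the tests below were chosen after the result they bear on was seen. In the first pattern, the set of 12 genes, reads shared between overlapping gene models are consistent with 3: Gm20708 summed with Afmid was at -0.072 ± 0.203, where Gm20708 or Afmid alone would give 0.719 or -1.71, and Gm28036 summed with Cpne1 was at -0.059 ± 0.137, where either alone would give 0.467 or -0.793. All 8 of the remaining lower genes passed with overlaps summed, most having no overlap to sum. The average length trend was small beside the 12 fold changes, as the correction kept 94.5% of their median size (2.42 before, 2.29 after). Over all genes it moved the log2 fold change by a median of 0.119, and the 12 were picked for large changes. The test could therefore hardly have come out otherwise, and it does not decide whether length had a part. After the correction only 7 still passed, and the others had an edgeR adjusted p of up to 0.0855. Losses particular to single long transcripts were not tested. With 10 splits of the 6 libraries into 3 and 3, of which 1, the real one, gave as many genes, a share under 0.05 cannot be reached; the real split gave 12 genes and the highest other split 3 (752 and 68 by DESeq2). For Gpam, Slc7a2, Gnal, Dlg1, Ppm1a, Slc19a2 and Tmem87b an effect of the melatonin treatment stays open and was not tested apart from the mice that received it.

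The second pattern is the rise of short genes of the ribosome and the respiratory chain, in libraries whose levels also follow transcript length. For cytosolic ribosomal protein genes the median of 0.57 lay above the central 95% of length- and expression-matched sets (up to 0.24). The list also passed after correction. The sets were off in length by a median of 9.9%. Once the trend of other genes was removed, the list's median was lower (0.34 ± 0.03 SE, against 0.57 ± 0.03). Both tests used the longest annotated transcript, which need not be the one counted (Rpl35a 2858 bases, Rps12 1795, Rps28 1443). Genes of 500 to 1000 bases had a median of 0.415. Whether length alone accounts for the rise of ribosomal protein genes therefore stays open. For oxidative phosphorylation genes the tests were divided. The median of 0.37 lay above the central 95% of matched sets (up to 0.24, off in length by a median of 13.2%). It went from 0.37 ± 0.05 to 0.11 ± 0.04, however, once the trend of other genes was removed, and the call ended because the shift itself shrank. For these genes length and treatment cannot be told apart, since the slopes of the libraries follow the groups except in glycerol replicate 3. Differences in RNA integrity between the muscles may produce such a trend and were not tested.

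The third pattern is the rise of immediate-early and heat shock genes. Length is argued against, as the median of 0.51 lay above matched sets (up to 0.15). Other cells left in the muscle stay open: per mouse, the erythroid list differed by -0.275 ± 0.621 between the groups (without glycerol+melatonin replicate 3 it was higher, camera adjusted p = 0.625), the macrophage list by 0.046 ± 0.154 and the lymphocyte list by 0.035 ± 0.304, and neutrophil markers rose mainly in 1 mouse. Another time of day may contribute: the score of Dbp, Tef, Hlf, Ciart, Per2, Per3, Nr1d1 and Nr1d2 minus Arntl, Npas2 and Clock, on log2(CPM + 0.1), was lower in all 3 glycerol+melatonin mice, by -0.51 ± 0.24, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, with Dbp sharing bases with Sphk2, which was at -0.95 ± 0.16. That size decides nothing, so a time of day, the handling of the muscle and the treatment, which can itself act on the clock, cannot be told apart.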
